A study of Drosophila melanogaster with 10 samples.

How the data were processed

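Total RNA of Drosophila melanogaster S2 cells was measured on single-colour Affymetrix arrays with biotin-labelled samples. Per the labels' protocols, cells received 10 µg of dsRNA in medium without serum for 1 h, were divided on day 3 and collected on day 7, and RNA was extracted by either of 2 Qiagen methods; which sample had which method is not given in the sources used here. The deposited table held 1 log2 value per probe set and sample. The authors made these log2 values with GCRMA, per the submitters' processing notes, a method that corrects for background by probe sequence, normalizes between arrays and summarises probes; its version, and whether the batches were normalized together, are not given in the sources used here. The log2 scale was taken from the values, which ran from 2.20 to 15.7. Between 50.5% and 51.8% of the probe sets of an array lay within 0.01 of the lowest value, and between 62.0% and 62.8% lay under 4, so low values have no dependable order and fold changes of dim genes are compressed.

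Samples were grouped by the labels' RNAi type into 5 control and 5 JIL-1 RNAi samples, and by the labels' batch. Probe sets were named from the platform annotation supplied with the data: of 18952 probe sets, 183 were array controls, 13647 had 1 gene, 402 several and 4720 none listed. Of the 13647, 13544 matched a gene of the Drosophila assembly Release 6 by gene ID, whose gene table gave current symbols, the chromosome arm and the start and end of each gene. These positions set the order of neighbouring genes, their overlaps and the nearness to centromeres, and no coordinates are printed. Genes of several-gene probe sets were not named. Array controls were left out, the probe set with the highest mean over all 10 samples stood for each gene, leaving 17104, and those with a mean above 4 were tested, 6721 in all (5852 with 1 gene name, 195 with several and 674 with none). Of these 5838 lay on a chromosome arm. Probe sets of a named gene that changed in opposite directions are given where they occur. Some genes of the lists, such as the roX RNAs and the Hsp70 genes, were not analysed here because no probe set that carried their name alone was among those tested.

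The values were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) with terms for group and batch, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. A fit of 4 means, 1 for each combination of batch and group, gave the change within each batch, the difference of these changes and the difference between the control samples. The 100 regroupings of the samples that keep the number of each group in each batch, the real one included, gave exact permutation tests whose smallest p is 0.01. Gene lists, 33 in number, were tested where 5 or more members were measured (23 lists), with camera at a preset correlation of 0.01, camera with an estimated correlation, and fry. Calls by chromosome arm were compared by Fisher's exact test, each arm against all other tested genes on an arm. The range of the X gap came from 2000 bootstrap samples of genes. These choices, the lists and the alternatives were fixed before the data were examined, except where the text says otherwise.

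Named genes were chosen by a rule: JIL-1; the 12 largest rises and 12 largest falls of named genes past the threshold with the same direction in both batches; for each list up to 4 members past the threshold with the smallest p, or the 2 with the smallest p where none passed; and for the difference between batches the 5 with the smallest adjusted p on each side. Genes named under this rule that lost their call when 1 sample was left out are mostly given as counts. Bounds for genes near the lower end of the scale were set after their values were seen: for a gene with any value under 4, the change was fitted again with values under 4 raised to 4 and is given as a lower bound. The permutation test of list medians, the scan of families by symbol, the signals of the array control probe sets and the level of 4 in these bounds, first set at 3, were also chosen after the data were seen.

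Alternatives were a fit without batch, no filter or a mean above 6, arrays set to a common median, quantile normalization, a variance trend with robust fit, array weights, every probe set as a row, probe sets without cross-hybridising types, the replicate number as a block, batch as a random block, leaving out each sample, and, for counts, a 1.5-fold minimum or an adjusted p under 0.1. Fits with the 3' minus 5' signal of Act5C or of GAPDH as a covariate, and with values under 4 raised to 4, were added after the data were seen. No libraries were duplicated: the SD of the difference between samples of the same batch and group was 0.155 to 0.264 over 8 pairs.

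The fit was tested on simulated data with the real means, batch effects and spreads, with 6721 genes in all. Of 50 genes changed by each size, 23 of those changed by 0.25, 45 by 0.5, 49 by 1 and 50 by 2 on the log2 scale were recovered for the comparison of JIL-1 RNAi with control RNAi, with 10 false calls. The simulated noise was independent between genes, and far fewer genes were changed than the 2397 called in the data. These rates therefore need not carry over to the real comparison. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.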

Results

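Gene expression was measured in Drosophila S2 cells, an embryonic line that resembles macrophage-like blood cells, after RNA interference (RNAi) against JIL-1. JIL-1 encodes a chromatin-bound histone kinase. Double-stranded RNA (dsRNA) against JIL-1 was compared with dsRNA against a sequence foreign to the fly. There were 10 samples, 5 control and 5 JIL-1 RNAi, in 2 labelled batches. Batch A held 3 control samples that received GST dsRNA and 2 samples that received a dsRNA from the 5' part of JIL-1. Batch B held 2 control samples that received EGFP dsRNA and 3 samples that received a dsRNA from the 3' part. The series names the samples biological replicates. Each array gave 18952 probe set values on a log2 scale, of which 6721 genes or unnamed probe sets with a mean above 4 were tested. The median of the tested values ran from 9.22 to 9.42 between arrays, and the number of arrays limits the precision. Values after a change are log2 differences with the standard error (SE) from a limma fit of 5 against 5 samples with a term for batch, and adjusted p-values are limma's with Benjamini-Hochberg adjustment. Where a gene had a value under 4 in any sample, its change and fold are given with such values raised to 4, as lower bounds.

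The JIL-1 transcript was lower in every sample that received JIL-1 dsRNA than in the controls of its batch. In batch A the 3 controls lay at 5.80 ± 0.15 (SD, n = 3) and both JIL-1 RNAi samples at 4.35. In batch B the 2 controls lay at 7.44 ± 0.14 (SD, n = 2) and the 3 JIL-1 RNAi samples at 5.76 ± 0.09 (SD, n = 3). Over both batches JIL-1, on arm 3L, fell by 1.56 (SE 0.08, adjusted p = 5.32e-07), which is a level 2.95-fold lower. No other of the 100 regroupings that keep the batch sizes gave a change as large (exact permutation, two-sided, p = 0.01, the smallest they can give). The control samples of the batches differed by 1.64 in JIL-1 (adjusted p = 2.57e-06), about as much as the knockdown. Without a term for batch the fit gave -1.26 with an adjusted p of 0.153.

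**Figure D1:**
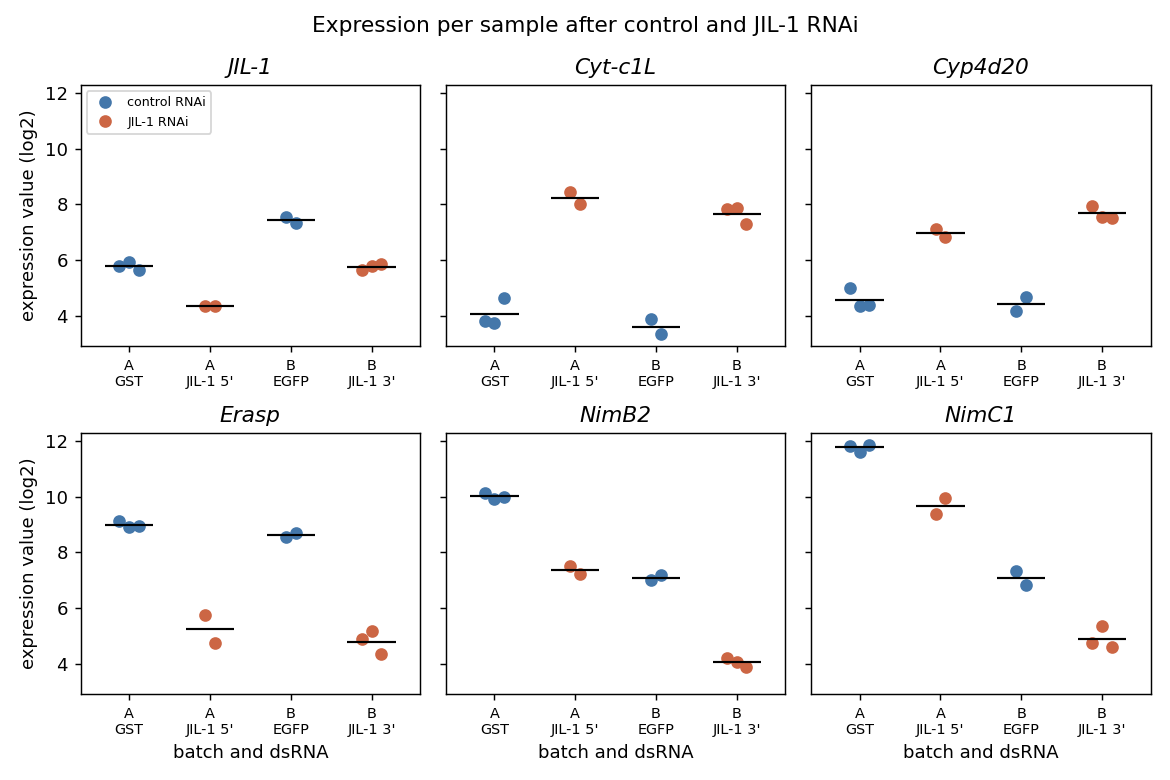
Expression values (log2, vertical axis) of 6 genes in each of the 10 samples, by batch and dsRNA (horizontal axis); points are samples and lines are means of each combination. JIL-1 was lower after JIL-1 dsRNA in both batches, Cyt-c1L and Cyp4d20 were higher, and Erasp, NimB2 and NimC1 were lower.

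The comparison of JIL-1 RNAi with control RNAi asks which transcripts follow the loss of the kinase. The largest rise was that of Cyt-c1L, a paralog of the respiratory chain subunit cytochrome c1, which was at least 14.3-fold higher (log2 3.84, SE 0.17, adjusted p = 1.86e-07), with 4 of its 5 control values under 4. Cyp4d20, a cytochrome P450, was 7.01-fold higher (2.81, SE 0.21), and SkpB, a Skp family protein of ubiquitin ligases, 3.68-fold higher (1.88, SE 0.14). The largest falls included Erasp, which was 13.7-fold lower (log2 -3.77, SE 0.20, adjusted p = 7.63e-07), and nahoda, 10.7-fold lower (-3.42, SE 0.17). NimB2, a secreted protein of the Nimrod family, was at least 7.11-fold lower (-2.83, SE 0.09), and Ugt37D1, a UDP-glycosyltransferase, 6.74-fold lower (-2.75, SE 0.07).

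In all, 2397 of the 6721 tested genes and probe sets changed (35.7%), of which 1396 rose and 1001 fell. Most changes were small: 130 rises and 341 falls reached 1.5-fold, 26 rises and 156 falls reached 2-fold, and 2 rises and 36 falls reached 4-fold. Among the 2397 were 2122 with a single gene name. The median change of all tested was 0.047. Besides those above, the largest rises of named genes were CG8301 (1.75), Asph (1.31), CG4586 (1.41), Apoltp (1.44), CG4872 (1.35), wdp (1.34), Ids (1.33), alpha-Est3 (1.02) and CG7860 (1.26). Apoltp encodes a lipid transfer apolipoprotein, wdp a leucine-rich repeat membrane protein and Ids a sulfatase. The remaining large falls were CG34330 (-3.77), Swim (-3.12), LManI (-2.13), Prx6c (-2.78) and CG15695 (-2.73), together with 3 genes near the lower end of the scale after JIL-1 RNAi. Swim encodes a secreted protein that binds Wingless, LManI a lysosomal mannosidase and Prx6c a peroxiredoxin. CG40006, firl and CG31769 lay under 4 in all 5 JIL-1 RNAi samples, and were at least 5.33-fold, 3.86-fold and 3.75-fold lower. Asph lay under 4 in all 5 control samples and was at least 2.48-fold higher. All of these genes passed the threshold, with adjusted p of 0.00674 for Ids and lower for the others in the fit of the values as given. Ids gave an identical value in 4 samples and Swim in 3, near the lower end for their probe sets. Over all 6721 tested, 74.9% had the same direction in both batches. Without a term for batch 501 genes passed, and without the filter on dim probe sets 1452 passed.

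Genes of the immune response were the list with the most falls. Over all tested genes and probe sets 20.8% rose and 14.9% fell. Of 14 measured members of the antimicrobial, Imd and Toll list, 8 fell (7 to 9 when 1 sample was left out) and none rose. They included Mtk, an antimicrobial peptide (-1.73, SE 0.27), PGRP-LF, a peptidoglycan recognition protein (-0.86, SE 0.14), Tep4, a thioester protein (-0.71, SE 0.08), and dl, the NF-kappa-B factor Dorsal (-0.56, SE 0.08). Adjusted over the list alone, 8 members fell and 1 rose. The median of the list was -0.58, and camera called it with an adjusted p of 0.002. With an estimated correlation the adjusted p was 0.695, and 12 of the 100 regroupings gave this list a camera p as small. The median of the list lay farther from 0 than in any other regrouping (exact permutation, two-sided, p = 0.01, adjusted over 23 lists 0.0383). This permutation test of list medians was added after the data were seen, and it asks only whether a list moved, not whether it moved more than other genes.

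Markers of blood cells fell in part. Of 19 measured plasmatocyte markers, 6 fell, also whenever 1 sample was left out, and 3 rose, with 1 to 4 when 1 sample was left out (4 rises and 6 falls adjusted over the list alone; camera adjusted p = 0.148, and 0.761 with an estimated correlation). NimC1, a phagocytosis receptor, was 4.42-fold lower (-2.14, SE 0.16), Sr-CI, a scavenger receptor, 2.46-fold lower (-1.30, SE 0.07), Ppn, a matrix protein, 1.87-fold lower (-0.90, SE 0.07) and drpr, an engulfment receptor, 1.68-fold lower (-0.75, SE 0.08). The median of the list was -0.10 (exact permutation p = 0.01, adjusted 0.0383), with -0.070 in batch A and 0.015 in batch B. Both measured crystal cell markers fell, PPO1 by -0.67 and PPO2 by -0.60, and of 6 lamellocyte markers CG15347 (-1.28) and PPO3 (-0.58) fell and 1 rose (median 0.089, mean -0.21, camera adjusted p = 0.534). Of the other cell type lists, 2 of 4 measured neuron and glia genes rose, moody (0.52) among them, and none fell. None of the 3 testis genes, the 1 fat body gene and the 1 muscle gene passed the threshold; bt, the muscle gene, differed between the batches.

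Rises among dosage compensation genes were small. Of the 6 measured members of the male-specific lethal complex and its recruitment factor, 5 rose, among them msl-2 (0.52, SE 0.10) and mle (0.26, SE 0.05), but only 2 rose without JIL-1 RNAi replicate 2, control replicate 4 or control replicate 5. The median of this list was 0.24 (camera adjusted p = 0.176, and 0.761 with an estimated correlation; exact permutation p = 0.01, adjusted 0.0383). Chromatin lists had rises and almost no falls. Of all tested genes 20.8% rose and 14.9% fell, and the rises in the trithorax and Polycomb lists lay near that share of rises. Of 17 interband and insulator genes 5 rose (3 without JIL-1 RNAi replicate 2) and 1 fell, with su(Hw) at 0.43 (SE 0.08), Jasper, a binding partner of JIL-1, at 0.29 (SE 0.06) and BEAF-32 at 0.24 (SE 0.06). Of 23 transcription elongation genes 7 rose (5 to 7 when 1 sample was left out), such as Cdk12 (0.41, SE 0.07) and Nelf-E (0.28, SE 0.05). Of 15 heterochromatin genes 4 rose, led by Su(var)3-3 (0.43, SE 0.06), and without JIL-1 RNAi replicate 1 only 1 rose. Of 14 trithorax group genes 3 rose (2 to 3 when 1 sample was left out), osa (0.40) and trx (0.41) among them, and of 14 Polycomb group genes 3 rose (1 without JIL-1 RNAi replicate 2), Sfmbt (0.27) among them. No member of the elongation, heterochromatin, trithorax and Polycomb lists fell. The medians in batches A and B were 0.19 and 0.025 for elongation, 0.17 and 0.022 for trithorax, and 0.11 and 0.022 for heterochromatin. They were 0.12 and 0.078 for Polycomb and 0.10 and 0.086 for interband and insulator genes. Over all tested they were 0.072 and 0.014. The camera adjusted p was 0.437 for the interband and insulator list, 0.412 for elongation, 0.69 for heterochromatin, 0.425 for trithorax and 0.45 for Polycomb. The exact permutation test of the medians gave adjusted p of 0.0383, 0.124, 0.0575, 0.0836 and 0.0575 in the same order. None of 3 measured histone genes passed.

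Small RNA and germ line genes moved both ways. Of 16 RNA interference genes 2 rose and 3 fell, and the falls included AGO3 (-0.86, SE 0.11) and aub (-1.19, SE 0.12), Argonautes of the piRNA pathway, while Hen1 rose (0.45, SE 0.10). Of 11 germ line genes 5 rose and 4 fell, and the rises included rhi (0.72, SE 0.06), swa (0.55, SE 0.10) and stwl (0.58, SE 0.06). AGO3 and aub belong to both lists and count among the falls of each. The median and mean had opposite signs in both lists, 0.052 and -0.075 for RNA interference and 0.16 and -0.004 for the germ line. Of 15 lipid genes 5 fell and 1 rose. Lsd-1, a lipid droplet perilipin, changed by -1.05 (SE 0.13), bgm, an acyl-CoA synthetase, by -0.91 (SE 0.09) and Lip4, a lipase, by -0.69 (SE 0.08). The median of the lipid list was -0.001 and its mean -0.19 (camera adjusted p = 0.148).

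Of 18 stress kinase and detoxification genes 5 fell and 2 rose, GstE2 (-0.82, SE 0.12) and GstD3 (0.34, SE 0.07) among them (median -0.16, camera adjusted p = 0.19, exact permutation p = 0.01, adjusted 0.0383). Of 7 JAK/STAT genes 2 fell and 1 rose, and the falls included et, an inhibitor of the pathway (-0.92, SE 0.06). Of 20 DNA damage and apoptosis genes 6 fell and 4 rose, with Dronc, an initiator caspase, at -0.41 (SE 0.07) and egr, a TNF ligand, at 0.28 (SE 0.05). Of 10 ecdysone genes 3 rose and 1 fell, Hr39 by 0.67 (SE 0.09) and br by 0.61 (SE 0.11), though 1 of the 4 probe sets of br had the opposite sign; the median of the list was -0.006 and its mean 0.068. Of 69 mitochondrial ribosomal protein genes 16 rose and 3 fell, of 27 proteasome genes 6 rose and 1 fell (median 0.093, exact permutation p = 0.01, adjusted 0.0383), and of 55 oxidative phosphorylation genes 6 rose and 5 fell. The rises among mitochondrial ribosomal protein and proteasome genes lay near the 20.8% of all tested genes that rose. The median of the mitochondrial ribosomal protein list was 0.23 in batch A and 0.015 in batch B. Of 35 cell cycle genes 4 rose and 1 fell, of 32 ribosomal protein genes 2 rose, of 11 glycolysis genes 3 fell and 1 rose, and of 11 chaperone genes 2 fell and 1 rose. The camera adjusted p of these lists was 0.148 or higher, and limma's fry, which tests whether a list moves on balance one way, called 13 of the 23 tested lists, 6 upward and 7 downward. Adjusted over the list alone, heterochromatin kept 3 rises, trithorax 2, elongation 6 and proteasome 5, cell cycle and ribosomal protein genes kept none, and oxidative phosphorylation kept 2 rises and 3 falls. No Hox or follicle cell gene of the lists was among those tested. With an estimated correlation no list passed. When 1 sample was left out, the rises ranged from 8 to 20 among mitochondrial ribosomal protein genes, 2 to 6 among proteasome genes, 2 to 8 among oxidative phosphorylation genes and 0 to 5 among cell cycle genes. They ranged from 1 to 6 among DNA damage and apoptosis genes, 2 to 4 among RNA interference genes, 0 to 2 among JAK/STAT genes, and 1 to 2 among ribosomal protein and among neuron and glia genes. The falls ranged from 2 to 7 among stress kinase and detoxification genes, 3 to 6 among DNA damage and apoptosis genes, 2 to 7 among oxidative phosphorylation genes, 1 to 5 among mitochondrial ribosomal protein genes, 1 to 2 among cell cycle, JAK/STAT and chaperone genes, and 0 to 2 among interband and insulator genes. The single rises among chaperone, glycolysis and lamellocyte genes were lost in some of these fits, and lists without a rise or without a fall gained at most 1.

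**Figure D2:**
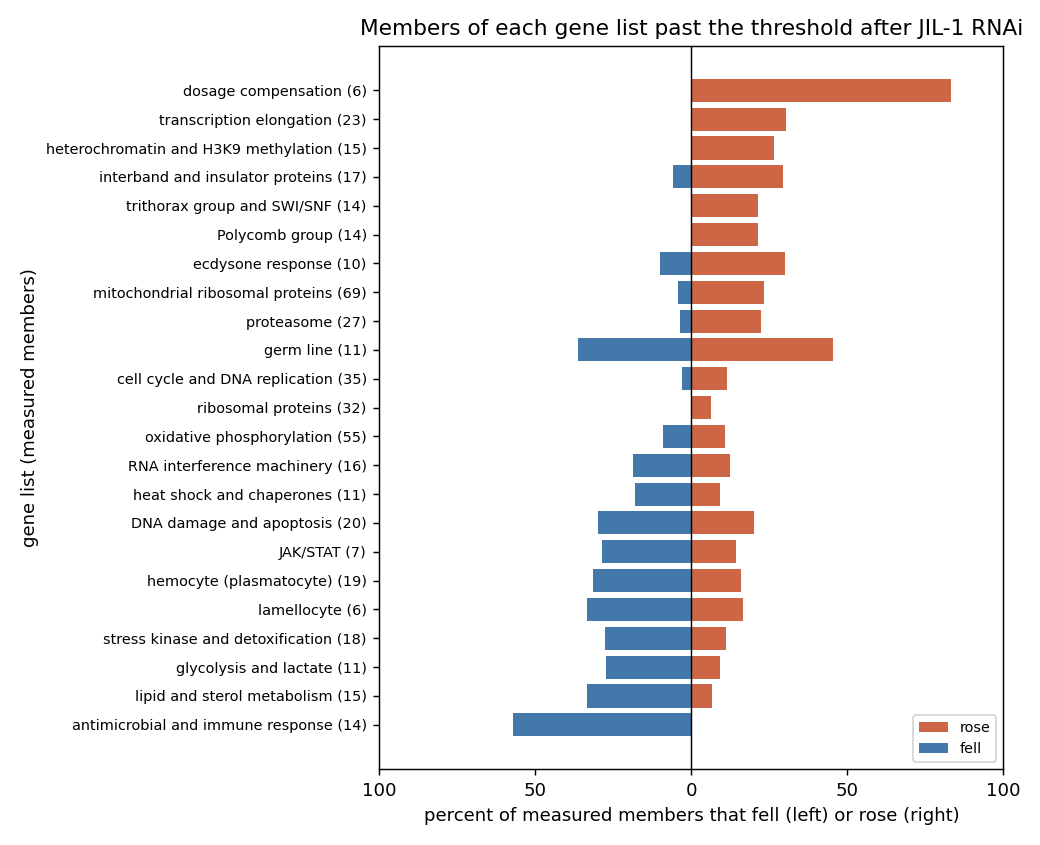
Percent of the measured members of 23 gene lists (vertical axis, with the number measured) that fell (left) or rose (right) past an adjusted p of 0.05 after JIL-1 RNAi (horizontal axis, percent). The immune list held 8 falls among 14 members and the dosage compensation list 5 rises among 6.

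Genes on the X chromosome were compared with autosomal genes because JIL-1 is known to be enriched on the X chromosome of males and S2 cells are male. Of 990 tested X-linked genes 137 rose (13.8%) and 196 fell (19.8%), whereas of 4807 genes on the large autosomes 1112 rose (23.1%) and 659 fell (13.7%). The median change was -0.049 on the X and 0.071 on the autosomes, a gap of -0.12 (bootstrap over genes, 95% range -0.14 to -0.10). X-linked genes were fewer among the rises (odds ratio 0.537, Fisher's exact test, two-sided, adjusted p = 1.73e-10) and more among the falls (odds ratio 1.55, adjusted p = 1.3e-05), with genes treated as independent. The X held 15 falls of at least 2-fold (1.52% of its genes) and the autosomes 122 (2.54%, Fisher's exact p = 0.0649). On 3R rises were more frequent (24.4%, adjusted p = 0.00736) and on 3L falls were less frequent (12.4%, adjusted p = 0.0435), but camera called neither arm (adjusted p = 0.309 for each, and 0.869 with an estimated correlation). Each arm was set against all other tested genes on an arm, the X included. The large autosomes together had 23.1% rises and 13.7% falls, so the X contributes to both differences. Neither arm was tested against the other autosomes alone. The 41 tested genes of chromosome 4 had a median of -0.049.

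The gap was -0.11 in batch A and -0.092 in batch B, and none of the other 99 regroupings gave a gap as far from 0 (exact permutation, two-sided, p = 0.01). Camera called the X lower with an adjusted p of 0.00743, and with an estimated correlation its adjusted p was 0.869. The control samples of batch B against those of batch A also showed a gap, of -0.096. Without the filter on dim probe sets the gap was 0. Between 50.5% and 51.8% of the probe sets of an array lay within 0.01 of the lowest value. Such rows can show almost no change and pull both medians towards 0, so this fit does not speak against the gap.

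**Figure D3:**
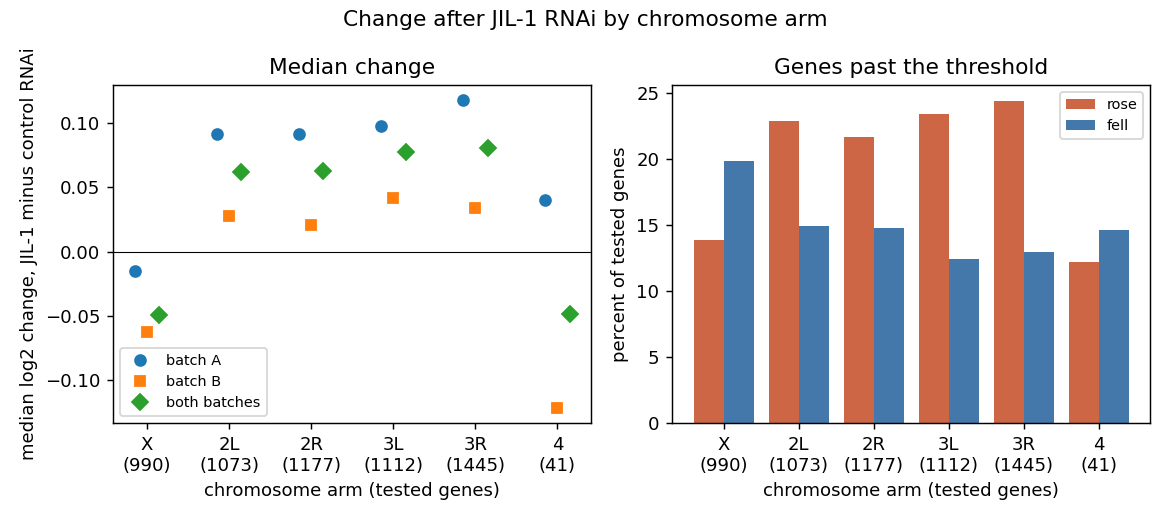
Median log2 change after JIL-1 RNAi (left, vertical axis) in batch A, batch B and both, and percent of tested genes that rose or fell (right, vertical axis), by chromosome arm with the number of tested genes (horizontal axis). The X had a median of -0.049 where the large autosomal arms lay between 0.062 and 0.08.

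Highly and weakly expressed genes changed by nearly the same median amount. With genes divided into 5 sets by mean level, the median change was 0.055 in the lowest set and 0.014 in the highest, a gap of -0.041 that 27 of the 100 regroupings equalled or exceeded (exact permutation, two-sided, p = 0.27). Large falls were unevenly spread, with 85 falls of at least 2-fold in the lowest set and 5 in the highest. With quantile normalization the gap was -0.072 (exact permutation p = 0.01). Without the filter it was 0.032 (exact permutation p = 0.03), but the lowest set then held only rows with a mean of 4 or less.

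Each batch used its own dsRNA against JIL-1, so the batches show which changes arose with either dsRNA. NimC1 changed by -2.11 in batch A and -2.18 in batch B, Erasp by -3.74 and -3.80, Ugt37D1 by -2.84 and -2.67, and Cyt-c1L by at least 4.02 and 3.67. In batch A 1894 genes changed (1162 rose and 732 fell) and in batch B 1184 (500 rose and 684 fell). Leaving out 1 sample gave 1202 to 1965 genes in batch A and 516 to 1296 in batch B, and array weights gave 1552 and 2556, so which batch had more changes depended on the fit. Of the genes called in each batch, 320 rose in both and 462 fell in both, where independent lists would share 86.4 and 74.5, and 7 went opposite ways. With quantile normalization batch B had 820 rises and 746 falls. Across the 6721 genes, which are not independent replicates, the changes of the batches correlated with Pearson's r 0.774 and Spearman's rho 0.679 (exact permutation, one-sided, p = 0.01 for each). The highest r of another regrouping was 0.729.

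**Figure D4:**
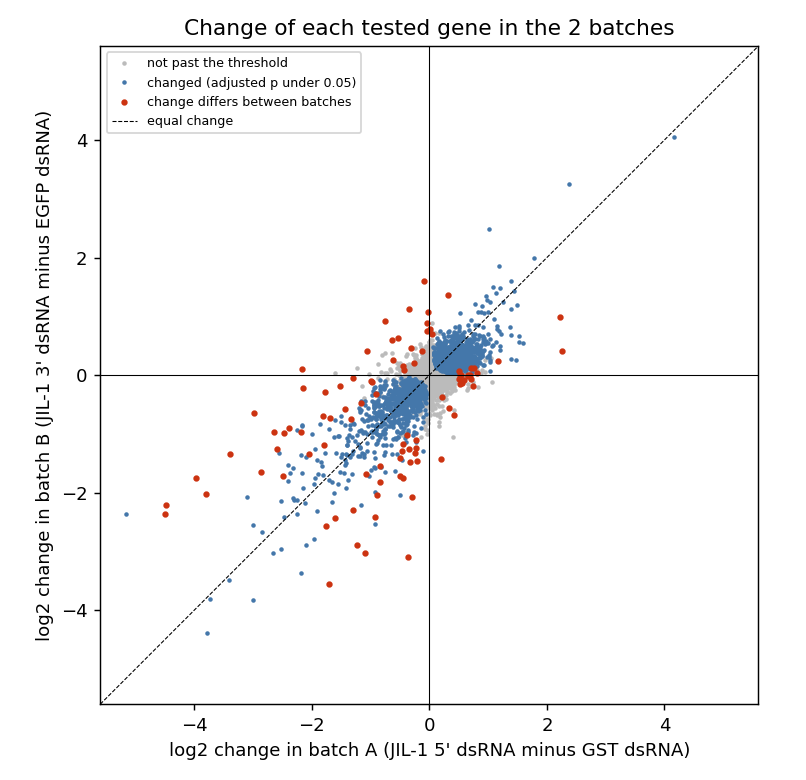
Log2 change of each tested gene in batch A (horizontal axis) and batch B (vertical axis), each point a gene or unnamed probe set. Blue points passed the threshold over both batches, red points had changes that differed between the batches, and r was 0.774 over all points.

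Some genes changed by different amounts in the batches. Obp99c, an odorant-binding protein, changed by -2.98 in batch A and -0.65 in batch B. CG3036 did not pass in batch A (0.20, adjusted p = 0.0574) and fell in batch B (-1.43), and CG5080 fell in batch A (-0.35) and rose in batch B (1.13). CG3376 (-1.30 and -2.30) and stw (-0.84 and -1.81) fell more in batch B. The interaction passed for 93 genes, 46 with a higher and 47 with a lower change in batch B, and for 993 at an unadjusted p under 0.05. Leaving out 1 sample gave 31 to 117 genes, with 31 without control replicate 5, and array weights gave 172. The difference for LManI, whose batch A values after JIL-1 RNAi lay under 4, was 0.22 with such values raised (adjusted p = 0.545). With arrays set to a common median the 103 genes that passed split into 62 and 41. In batch B the 3' signal of the actin gene Act5C exceeded its 5' signal by 2.94 ± 0.23 (SD, n = 2) in controls and 2.35 ± 0.08 (SD, n = 3) after JIL-1 RNAi. In batch A the values were 0.84 ± 0.11 (SD, n = 3) and 0.81 ± 0.05 (SD, n = 2). For GAPDH they were 0.50 ± 0.10 (SD, n = 3) in controls and 0.67 ± 0.11 (SD, n = 2) after JIL-1 RNAi in batch A, and 1.39 ± 0.22 (SD, n = 2) and 1.34 ± 0.08 (SD, n = 3) in batch B. Each dsRNA lies in 1 batch, so dsRNA and batch cannot be told apart.

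The control samples of the batches differed more than the RNAi groups did. Between EGFP controls in batch B and GST controls in batch A, 4194 genes differed (62.4%), 2535 higher and 1659 lower in batch B. With arrays set to a common median 1854 were higher and 2464 lower, and the median difference of all genes before that step was 0.10. The SD of the differences over genes was 0.72, against 0.44 for the change in batch A and 0.39 in batch B. The mean of the poly-A spike probe sets, which are bacterial control sequences, was 2.45 ± 0.05 (SD, n = 5) in batch A and 8.65 ± 0.24 (SD, n = 5) in batch B, and that of the hybridisation controls 9.51 ± 0.14 and 11.51 ± 0.10 (SD, n = 5 each).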

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

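The tests of regroupings of the samples, of the immune and plasmatocyte genes, of values near the lower end of the scale and of the GAPDH signal were chosen only after the results were seen, except the test of list counts. The regroupings kept the batch sizes, 100 with the real one.

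The real grouping gave 2397 changed genes and the highest other count was 1, so chance is argued against for this count (1 of 100, the smallest share possible). The correlation between the batches was also the highest of the 100, at 0.774 against 0.729 for the next. Regroupings that keep part of the real groups in both batches can correlate too, so the small margin says little either way. For the number of gene lists chance cannot be excluded: 76 of the 100 regroupings gave as many lists past the camera threshold as the 1 of the real grouping, and the highest other gave 7. For the gap between highly and weakly expressed genes 27 of 100 regroupings were as far from 0, the farthest other at 0.089, so chance cannot be excluded there.

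X-linked genes were lower than autosomal genes after JIL-1 RNAi by -0.12, and no other regrouping was as far from 0 (1 of 100, farthest other 0.081). A difference in expression level is argued against, since the gap to autosomal genes matched on mean level was -0.117 (95% range -0.131 to -0.101). The 95% ranges here resample genes, not samples, and so do not measure how far the gap varies between samples. RNA integrity as the actin signal measures it is also argued against as the whole cause. In batch A, where the 3' to 5' signal of actin was alike in the groups, the gap was -0.114 (95% range -0.136 to -0.0944). GAPDH gave 0.67 after JIL-1 RNAi and 0.50 in controls in batch A, and 1.34 and 1.39 in batch B. With its signal as a covariate the gap was -0.116 (95% range -0.133 to -0.0994). The groups differed little in GAPDH, and in opposite directions in the 2 batches. This fit could therefore hardly move the gap, and no conclusion is drawn from it. Array or labelling differences of the kind that separate the batches stay open, because the control samples of the batches showed a gap of -0.0958 (95% range -0.132 to -0.0531), which met neither bound set beforehand. The median was -0.015 on the X and 0.099 on the autosomes in batch A, and -0.062 and 0.030 in batch B. Since values were normalized between arrays, the gap shows only the X relative to the autosomes, not which of them moved. A lower output of the X relative to the autosomes may be a biological explanation. It is a hypothesis that cannot be separated from array or labelling differences here.

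Of 33 members of the immune and plasmatocyte lists 14 fell, a minority but a larger share than the 14.9% of all tested genes. Neither list passed with an estimated correlation. An off-target effect of a single dsRNA is argued against for the 9 of these 14 (64.3%) that fell past the threshold within both batches, each with its own dsRNA. It stays open for the other 5. RNA integrity as the actin signal measures it is argued against for the 11 (78.6%) that fell within batch A, where that signal was alike. The GAPDH signal differed little between the groups beside the batch term, so its covariate could hardly move the changes and decides nothing. With the GAPDH covariate the median of the 14 was -0.715, against -0.71 without it, with all 14 past the threshold. With the actin covariate it was -0.797 and 11 of the 14 stayed past the threshold; CecB (-0.66, SE 0.16, before and -0.58, SE 0.22, after), eater (-0.36, SE 0.08, and -0.29, SE 0.11) and Hml (-0.29, SE 0.07, and -0.19, SE 0.08), named after their values were seen and the 3 that did not pass within batch A, lost the call through smaller changes and larger SE, so integrity stays open for part of their falls. For loss of a plasmatocyte-like part of the culture, 3 plasmatocyte markers rose over both batches (1 to 4 when 1 sample was left out). Within both batches 0 rose, which met neither bound. A loss of cells that carry all 19 measured markers alike is argued against. Of the 19, 10 did not pass and the median was -0.10, where NimC1 changed by -2.14. Loss of cells that carry only some of the markers stays open. A response of the cells to the loss of JIL-1 may be the explanation, and it was not tested apart from these.

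Between the batches 93 genes changed by different amounts, by the test of the difference itself. Of these, 82 (88.2%) also differed between the control samples, against 62.4% of all tested. Both comparisons use the same control samples, so an excess is partly built in and no cause is drawn from it. Fold changes compressed in 1 batch are argued against as the cause of the set, since the larger change lay in the same batch for 55.9% of the genes, 52 in batch A and 41 in batch B. Values near the lower end of the scale account for a part at most: 16.1% of the 93 genes, 15 in number, had a mean under 4 in 1 or more combinations of batch and group, against 2.17% of all tested, and with values under 4 raised to 4 the count was 114. The dsRNAs and the processing of the batches cannot be told apart for the 93 genes, since each batch holds its own pair of dsRNAs.

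Among named genes the change in batch B minus that in batch A was -0.70 for aub, 0.53 for bt, -1.63 for CG3036, 2.21 for CG31769, 2.05 for CG31974, -2.73 for CG32985, -1.001 for CG3376, 1.48 for CG5080, 2.27 for firl and 0.67 for GstE2. It was -1.85 for Ids, 1.78 for LManI, 1.498 for Mtk, 2.33 for Obp99c, -0.78 for RpS19b, -0.97 for stw and 2.13 for Swim. For CG31769, CG31974, CG32985, firl, LManI and Swim at least 1 combination of batch and group had a mean under 4, so the size of the difference is not dependable. With values under 4 raised to 4 the difference for LManI was 0.22 (adjusted p 0.545) and no longer passed. Ids gave the identical value in 4 samples, and RpS19b in 2 with 8 of 10 samples within 0.2 of it, near the lower end for their probe sets, so these differences are not dependable either.

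A single sample stood far from the other 4 of its group in 5 of 266 sets of values. Chance gives about 1 in 20 where samples are alike, but each group holds both batches, so the count cannot be set against chance here and the values are only described. They were Dcp-1 at 6.44 in JIL-1 RNAi replicate 1 (others 6.87 to 7.01), firl at 3.15 in JIL-1 RNAi replicate 1 (others 2.35 to 2.51) and Ibf2 at 9.89 in control replicate 3 (others 9.77 to 9.80). In control replicate 1 nahoda was at 8.25 (others 8.67 to 8.75) and vir-1 at 11.9 (others 11.2 to 11.4).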

How the results depend on the processing

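The direction of the change of JIL-1, of the correlation between the batches and of every named gene past the threshold held under every alternative run. The change of JIL-1 lost its call without batch (-1.26, adjusted p 0.153) and has no value with a mean above 6, since its own mean is lower. Leaving out 1 sample gave JIL-1 changes from -1.60 to -1.50, 1763 to 2261 changed genes, r from 0.745 to 0.774 and X gaps from -0.12 to -0.10. It gave 1202 to 1965 genes for batch A (1242 and 1202 without JIL-1 RNAi replicates 1 and 2) and 516 to 1296 for batch B (757 without JIL-1 RNAi replicate 4, 587 and 516 without control replicates 4 and 5). It gave 31 to 117 genes for the difference between the batches (55 without JIL-1 RNAi replicate 4, 44 and 31 without control replicates 4 and 5) and 1 to 2 lists (2 without JIL-1 RNAi replicate 5 or control replicate 4). Level gaps ran from -0.059 to -0.016 and genes different between the control samples from 3264 to 4187. Where 1 sample was left in a combination it is assumed to vary like the others.

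Changed genes numbered 501 without batch, 471 with a 1.5-fold minimum, 1452 without the filter, 1203 with the replicate block and the batch term and 797 with the replicate block alone. Without the filter batch A had 1192, batch B 734 and the lists 11, the X gap was 0 and the level gap turned to 0.032. Array weights gave 2556 genes in batch B and 172 for the difference. Quantile normalization made the level gap -0.072 with an exact permutation p of 0.01. Lists past the threshold were 0 with an estimated correlation, 0 without batch, 2 without cross-hybridising probe sets and 4 with the actin covariate, which was chosen after seeing the data. With the replicate block the X gap was -0.119 (exact permutation p 0.1) with the batch term and -0.12 (p 0.11) without it. Without the filter the X gap and the level gap rest largely on rows at the lower end of the scale. The causes of the other shifts were not tested. The replicate numbers do not pair the samples: number 3 lies in different batches, its deviations correlated at -0.77, and only number 4 correlated best with its own partner.

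With the actin covariate 1646 genes changed, with the GAPDH covariate 2038 and with values under 4 raised to 4 2390, the last of which gave 114 for the difference between the batches; these fits were also added after seeing the data. Of 124 named genes, 116 past the threshold, 24 lost their call in at least 1 fit without a sample, 26 with the actin covariate, 7 with the GAPDH covariate and 79 without batch, and 4 without a call changed sign in some fit.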

Other observations

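Families of genes that share the opening letters of their symbols were examined after the data were seen, 55 with at least 6 tested members. Cytochrome P450 genes mostly fell: of 22 genes whose symbol opens with Cyp, which include the cyclophilins Cyp1 and Cyp40, 15 fell and 4 rose. The falls included Cyp28a5 (-2.19 with values under 4 raised to 4, SE 0.10), Cyp6a23 (-1.92, SE 0.24) and Cyp12a5 (-1.69, SE 0.13), whereas Cyp310a1 rose (0.99, SE 0.11). Of 7 UDP-glycosyltransferases (Ugt) 6 fell, such as Ugt35C1 (-1.68 with values under 4 raised to 4, SE 0.13), and of 6 serpins (Spn), which inhibit proteases, 5 fell, such as Spn77Ba (-1.45, SE 0.08). The camera adjusted p was 0.000191 for Cyp and Ugt and 0.00422 for Spn, and with an estimated correlation the adjusted p was 0.538, 0.497 and 0.724. Medians were -0.53, -0.40 and -0.41, none equalled in other regroupings (exact permutation p = 0.01, adjusted over 55 families 0.0367). Pex, with 1 rise and 1 fall among 9 genes, Atg and Rab gave the same permutation p. It asks only whether a family moved, and does not set Cyp, Ugt and Spn apart. Camera also called Vha (3 of 9 fell, adjusted p = 0.0183) and Nepl (3 of 6 fell, 0.0238), each at 0.538 with an estimated correlation.

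Some genes of the core transcription and nuclear pore machinery rose by small amounts. Of 21 RNA polymerase subunit genes (Polr) 11 rose (7 to 12 when 1 sample was left out) and none fell, such as Polr3G (0.49, SE 0.09) and Polr1E (0.43, SE 0.07), with a median of 0.34 in batch A and 0.086 in batch B. Of 19 nucleoporin genes (Nup) 8 rose (4 to 10 when 1 sample was left out) and none fell, Nup43 (0.46, SE 0.06) and Nup133 (0.44, SE 0.08) among them. The camera adjusted p was 0.00993 for Polr and 0.038 for Nup, and 0.868 for each with an estimated correlation, so neither family passed then.

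CG40006 was the only one of 17104 genes and unnamed probe sets that lay under 4 in all JIL-1 RNAi samples and above 6 in all controls, and no other regrouping gave any; these levels were chosen after the values were seen.

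Both of the following tests were set before their results were seen. Neighbouring genes may change together. The mean product of the changes of adjacent tested genes on an arm, without cross-hybridising probe sets, was 0.0183, above the highest of 1000 shuffles (0.0083), and the correlation of 5017 neighbouring pairs was 0.126. Without pairs that overlap or share the start of a symbol the correlation was 0.101 over 4241 pairs. In a comparison that was not part of the test set beforehand, no other regrouping gave as high a mean product (1 of 100, highest other 0.0092). The mean product grows with the size of the changes, and the real grouping had 2397 changed genes where another had at most 1. This comparison therefore cannot tell whether neighbours were more alike in the real grouping. The difference between the control samples of the batches showed a correlation of 0.119 too, so correlated neighbours are not particular to JIL-1 RNAi.

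Genes next to the centromeres may respond apart from the rest. The 150 tested genes nearest the centromeres of X, 2L, 2R, 3L and 3R had a median change lower by -0.065 than the rest of these arms, as far from 0 as 3 of the 100 regroupings (exact permutation p = 0.03). The difference was -0.062 in batch A and -0.033 in batch B, but -0.099 between the control samples of the batches, and on the X it was 0.096, opposite to the autosomal arms. Array or labelling differences stay open as the explanation.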
